A study of Arabidopsis thaliana with 12 samples.

How the data were processed

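The series holds 12 single-colour microarrays of total RNA from shoots of Arabidopsis thaliana Col-0, in 4 groups of 3 arrays. The groups were taken from the sample titles: early control, early drought, late control and late drought. Control plants were watered regularly, and water was withheld from drought plants from an age of 3 weeks. The early harvest was on day 8 and the late harvest on day 11 of the treatment.

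Per the file headers, each spot's intensity was read with Agilent Feature Extraction 10.7.3.1 (protocol GE1_107_Sep09) from 62976 features per array, and its processed signal is background-subtracted and detrended across the array but not normalised between arrays. Per the labels' protocols, RNA was extracted with Trizol, purified on spin columns and labelled with Cy3. The deposited value table holds log2 values relative to each probe's median over the 12 arrays. Checked against the scanner files, that table matched the log2 processed signal minus each array's 75th percentile and minus the probe's median, with correlations across probes from 0.991 to 0.999 per array. No spot was marked as saturated.

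The analysis started from the processed signal of the scanner files. Spots marked as non-uniform or as population outliers were left out, replicate spots of a probe were averaged, and 33 probes with all spots marked on some array were dropped. Of 43603 non-control probes, 34285 were named to 1 locus through the RefSeq accession that the files give and the reference gene table (assembly TAIR10.1), and 9318 had no locus. No coordinates are printed, because the build of the array design differs from the reference table or is not named. The 34285 named probes cover 25383 loci, of which 6919 have several probes, and 25363 loci kept a probe after that step. The brightest probe by mean log2 level over the 12 arrays stood for its locus. A gene was tested if that probe was well above background on all 3 arrays of at least 1 group, which left 19734 genes and set aside 5629. Gene names come from the reference table. A symbol can belong to more than 1 locus there, so list members were matched by locus.

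The log2 processed signal minus each array's 75th percentile was fitted with limma 3.58.1 in R 4.3.3, with a mean per group over all 12 arrays, and moderated with eBayes. The comparisons were early drought minus early control, late drought minus late control, the difference between these responses (late minus early), and late control minus early control. Adjusted p values are Benjamini-Hochberg values from limma over the 19734 genes, and a gene was called at an adjusted p under 0.05. Errors given after ± are standard errors of the log2 difference unless SD is written, with n = 3 arrays per group. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

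The comparisons, tests, gene lists, the rule for named genes and a set of other settings were written before the data were examined. The 29 lists hold 452 loci. They cover drought, hormone, photosynthesis, growth, defence and clock genes, with markers of guard cells, roots, and flowers or seeds as other cell types that the tissue could hold. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 29 lists, with an estimated correlation and with fry as alternatives. The ribosomal list was built from gene descriptions and also holds chloroplast proteins whose description names no organelle. The plan moved a listed symbol to the locus that the reference gives for it. For CAO, CHI and PAP2 that locus is another gene, so the listed loci were kept, and moving them was run as an added alternative. DHAR1 had no probe.

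By the rule for named genes, each drought comparison names the 6 largest rises and 6 largest falls among called genes that have a symbol, are well above background on all 6 arrays and do not overlap between groups. It adds the 3 largest lower bounds among called genes not above background on any of the 3 arrays of a group, RD29A, RD29B, RAB18, NCED3 and P5CS1 whatever they show, and up to 4 members of each list with the smallest p. Lists of 6 or fewer members may be named in full. The late minus early comparison and the control comparison name the 4 largest rises and 4 largest falls. A lower bound sets each dim array to its own floor, the lowest scaled value of a spot well above background on that array, or to the gene's value where that is higher. It holds for the main scaling only, and other settings could give smaller folds. Genes named outside this rule are marked as chosen after their values were seen.

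The fit was tested on simulated data first. With 19734 genes and arrays drawn from the spread of these data for the late comparison, it called 35 of 100 genes changed 2-fold and 80 of 100 changed 4-fold, all with the right sign. It made 3 false calls there, and it called the 1 shifted list and no other. The simulated genes varied independently, with the same spread in all groups and no effect of array signal. The simulation therefore does not show how many false calls, of lists above all, arise in these data.

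The other settings fixed with them were quantile normalisation, median centring, the deposited value table, no background filter or a stricter one, the mean of all probes of a gene, the replicate number, the slide as a fixed or random block, the row on the slide for the control comparison, an intensity trend, only the arrays compared, an added 2-fold threshold, and each array left out in turn. The planned normexp correction used the mean signal, which the files do not hold, so it was run on the median signal instead. Alternatives added after seeing the data were that correction, the array signal as a covariate, the row on the slide in the other comparisons, single control arrays, and a fit without early control replicates 1 and 3, whose signal was lowest. For that last fit the background filter was first recomputed on the arrays kept. After its counts were seen, the gene set was fixed to that of all 12 arrays, and both versions are reported.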

Results

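Messenger RNA levels were measured in shoots of Arabidopsis thaliana (Col-0) with 1 array per sample. The series asks how the shoot transcriptome responds to drought, with water withheld from plants 3 weeks old and shoots harvested on day 8 (early) or day 11 (late). Watered controls were harvested on the same days. Each of the 4 groups holds 3 arrays, and this number limits the precision. Nothing in the labels states that the replicates came from separate cultures, so the p-values measure the spread between these samples only. Of the 19734 genes tested, 16218 were well above background on all 12 arrays.

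Early control replicates 1 and 3 had the weakest signal. The 75th percentile of the processed signal was 246, 779 and 253 in early control replicates 1, 2 and 3, against 945, 1456 and 1243 in early drought. In late control it was 624, 1141 and 1450, and in late drought 1286, 1721 and 1837. Early control replicates 1 and 3 had 36260 and 36218 spots well above background and replicate 2 had 40981, while the other groups had 42205 to 44905. The median signal of the spike-in control probes was not low on replicates 1 and 3, at 318 and 342 against 154 to 296 on the other arrays. Feature Extraction marked early control replicate 3 for evaluation and the other arrays as in range. All early arrays and late control replicates 1 and 2 share slide 1, and late control replicate 3 and all late drought arrays share slide 2. The median SD of log2 levels across genes was 0.34 in early control, 0.15 in early drought, 0.31 in late control and 0.19 in late drought.

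**Figure D1:**
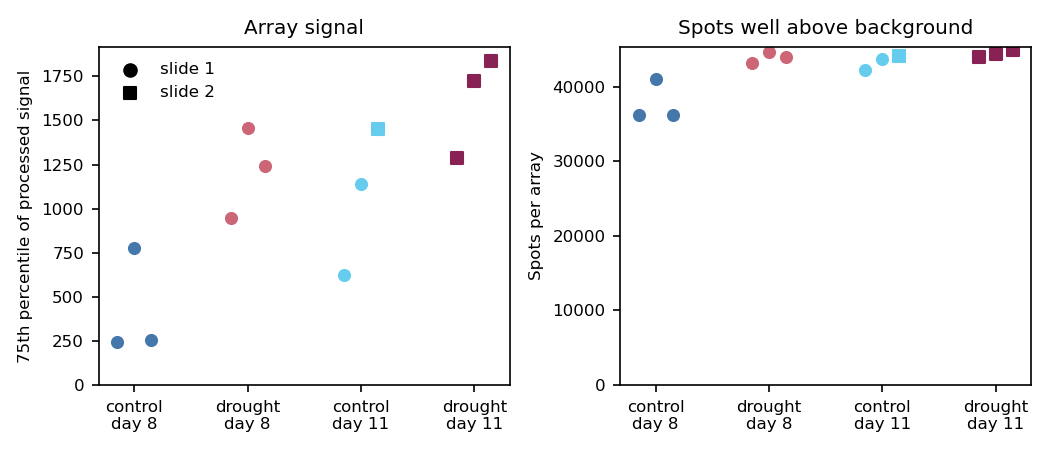
The left panel plots the 75th percentile of the processed signal of each array and the right panel the number of spots well above background, by group, with circles for slide 1 and squares for slide 2. Early control replicates 1 and 3 lie lowest in both panels, at 246 and 253 for the signal and at 36260 and 36218 spots.

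After 11 days without water, dehydrin and PP2C phosphatase genes were higher than in watered shoots of that day, and lists of growth and photosynthesis genes were lower. None of the lists that fell passed with an estimated correlation (adjusted p = 0.0632 at the smallest, for chlorophyll synthesis). Among called genes with a symbol that were above background on all 6 arrays and whose groups did not overlap, the largest rise was TSPO, a membrane protein induced by abscisic acid, at 8.06 ± 0.45 on the log2 scale (267-fold, n = 3). LEA4-5 rose by 7.29 ± 0.40 and the dehydrin LTI30 by 7.20 ± 0.49. The heat shock factor HSFA6A rose by 6.99 ± 0.42, the sugar transporter SAG29 by 6.85 ± 0.81 and HIPP22 by 6.57 ± 0.28. The largest falls among these genes were -6.39 ± 0.50 for XTH6, a cell-wall enzyme, -6.17 ± 0.38 for the growth regulator PRE1, -6.10 ± 0.38 for GER3, and -5.79 ± 0.58, -5.74 ± 0.62 and -5.59 ± 0.60 for the defensins PDF1.3, PDF1.2b and PDF1.2c. Genes not above background in any late control array were at least 286-fold higher for DAA1, at least 226-fold higher for XERO1 and at least 162-fold higher for GASA3.

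The drought markers chosen beforehand all rose at day 11. RD29A rose by 4.53 ± 0.33, RD29B by 5.97 ± 1.02 and the dehydrin RAB18 (AT5G66400) by 5.24 ± 0.39. NCED3, the rate-limiting enzyme of abscisic acid synthesis, rose by 3.20 ± 0.27 and P5CS1, of proline synthesis, by 3.00 ± 0.27. Each was higher in all 3 drought arrays than in the 3 control arrays, with limma adjusted p from 1.01e-06 for RD29A to 0.000521 for RD29B.

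In the whole late comparison 9490 genes were called, 4279 higher and 5211 lower. With slide as a block, where the only late control on the slide of the drought arrays is replicate 3, the count was 4676, with 1855 higher and 2821 lower. Requiring at least 2-fold gave 6198 genes.

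**Figure D2:**
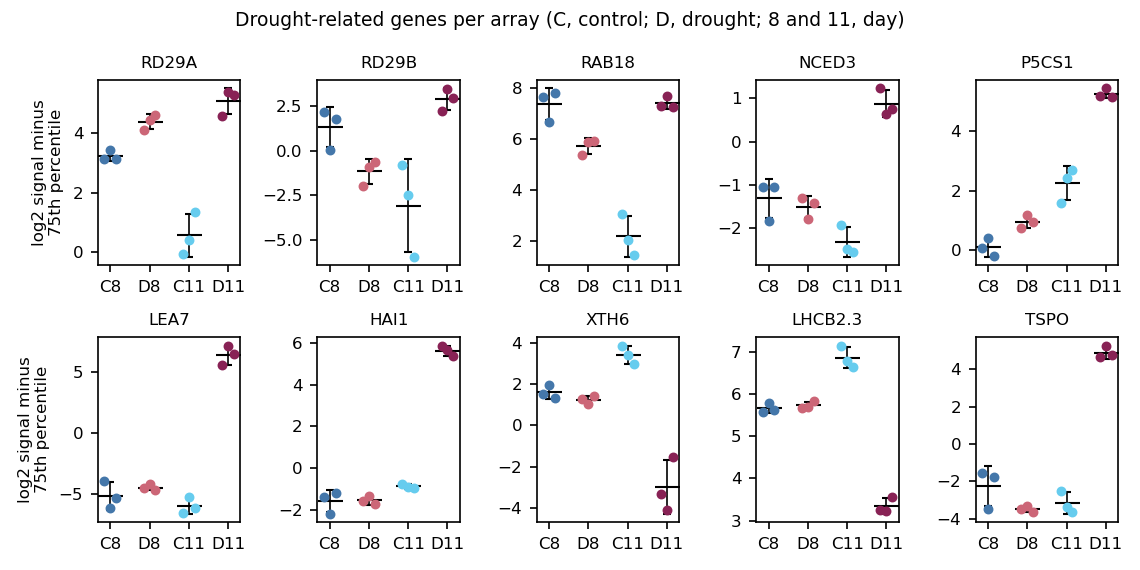
Points are the log2 signal minus the array's 75th percentile of 10 drought-related genes on each array, with the mean (dash) and SD (bars, n = 3 arrays) of control (C) and drought (D) at days 8 and 11. RD29B, RAB18 and NCED3 are higher in drought than in control at day 11, by 5.97, 5.24 and 3.20, and had differences of -2.50, -1.65 and -0.19 at day 8, where RAB18 was called, RD29B only in other settings such as slide as a block, and NCED3 not.

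Of the 29 lists, 21 passed camera with the preset correlation in the late comparison, 11 upwards and 10 downwards. With an estimated correlation only 2 of these passed, the dehydrins and the clade A PP2C phosphatases, and neither did so in the fit without early control replicates 1 and 3 (adjusted p = 0.112 with an estimated correlation). The median late difference over all genes was -0.05, and no list among the 21 turned its direction in any of the alternatives run. Each of the 21 lists has its value with slide as a block beside it.

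Among the 20 dehydrin and LEA genes, proteins that protect drying cells, 19 rose and 1 fell, and the counts were the same when adjusted over the list alone. The list median was 4.37 (adjusted p = 6.23e-12 with the preset and adjusted p = 0.0320 with an estimated correlation), and 4.26 with slide as a block. LEA18 was at least 69.8-fold higher in the main scaling. LEA7 had a mean level of 6.36 ± 0.77 (SD) in drought and -5.96 ± 0.68 (SD) in control, where 2 of 3 arrays were above background. COR15B, chosen after its values were seen, was the member that fell, by 1.04 ± 0.22 on the log2 scale, and its call was lost with slide as a block (adjusted p = 0.0532).

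All 9 clade A PP2C genes, which encode phosphatases that repress abscisic acid signalling, rose, also when adjusted over the list alone. HAI1 rose by 6.53 ± 0.25, ABI2 by 2.69 ± 0.16 and HAI2 by 5.39 ± 0.43, and AHG1 was at least 18.7-fold higher in the main scaling. The smallest rise of AHG1 in other settings was 1.77 on the log2 scale. The median was 2.69 (adjusted p = 5.31e-08, and adjusted p = 0.0320 with an estimated correlation), and 2.77 with slide as a block. Of 9 PYL abscisic acid receptor genes, 8 fell and 1 did not pass, and 8 fell adjusted over the list alone. PYL4 fell by 2.36 ± 0.26 and PYL8 by 2.50 ± 0.29 on the log2 scale. The list's median was -1.98, -1.91 with PYL6 at its bound, and -1.67 with slide as a block, where 5 genes passed (adjusted p = 0.000240 with the preset and adjusted p = 0.0755 with an estimated correlation).

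Of 12 genes of abscisic acid metabolism, 9 rose, 1 fell and 2 did not pass, with the same counts adjusted over the list alone. Beside NCED3, the genes for the catabolic enzymes CYP707A1 and CYP707A3 rose by 3.66 ± 0.20 and 1.94 ± 0.22, and the biosynthesis gene ABA2 fell by 1.71 ± 0.21. The median was 1.94 (adjusted p = 0.000263, and adjusted p = 0.0518 with an estimated correlation), and 1.48 with slide as a block. All 14 drought transcription factors measured rose, also adjusted over the list alone, with RD26 at 4.38 ± 0.26 and ABF2 at 2.22 ± 0.16. Their median was 2.22 (adjusted p = 2.53e-09, and adjusted p = 0.0635 with an estimated correlation), and 2.08 with slide as a block.

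All 6 proline genes rose, also adjusted over the list alone: beside P5CS1, P5CDH, which degrades proline's intermediate, rose by 1.17 ± 0.23, although its call was lost with slide as a block and with the mean of its probes. The median was 1.36, and 0.98 with slide as a block, where 1 of the 6 genes passed (adjusted p = 0.00246 with the preset and adjusted p = 0.0751 with an estimated correlation). Of 14 anthocyanin genes, 13 rose and 1 fell, with the same counts adjusted over the list alone. The regulator TT8 rose by 5.59 ± 0.36, and the enzyme genes F3'H and 5MAT by 5.22 ± 0.41 and 5.04 ± 0.40. FLS1, which makes flavonols and was chosen after its values were seen, was the member that fell, by 0.75 ± 0.24, a call lost in 6 of 22 settings: quantile normalisation, slide or row as a block, and without late control replicate 2, late drought replicate 2 or late drought replicate 3. The median was 4.90 (adjusted p = 3.08e-08, and adjusted p = 0.134 with an estimated correlation), and 3.99 with slide as a block.

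Photosynthesis genes fell together at day 11. Of 40 light-harvesting and photosystem genes, 38 fell and 2 did not pass, and 40 fell adjusted over the list alone. LHCB2.3 fell by 3.52 ± 0.18, PSBQ1 by 2.95 ± 0.25 and PSAH2 by 2.58 ± 0.21 on the log2 scale. The median was -1.49, and -1.12 with slide as a block, where 21 of the 40 genes passed (adjusted p = 6.44e-12 with the preset and adjusted p = 0.227 with an estimated correlation). Of 15 Calvin cycle genes, 13 fell and 2 did not pass, and 15 fell adjusted over the list alone. GAPA2 fell by 2.34 ± 0.26 and PGK1 by 1.32 ± 0.19. Their median was -1.32, and -1.07 with slide as a block, where 3 of the 15 genes passed (adjusted p = 0.000104 with the preset and adjusted p = 0.220 with an estimated correlation). Of 13 chlorophyll synthesis genes, 11 fell and 2 did not pass, with 11 adjusted over the list alone, and CHLM fell by 2.54 ± 0.21 and PORB by 2.32 ± 0.22. Their median was -1.68, and -1.60 with slide as a block (adjusted p = 5.33e-06 with the preset and adjusted p = 0.0632 with an estimated correlation).

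Of 14 senescence genes, 10 rose and 4 did not pass, and 11 rose adjusted over the list alone. NYE2 and PAO, which act in chlorophyll breakdown, rose 19.7-fold and 4.29-fold, and the regulator ORE1 rose by 2.24 ± 0.24 on the log2 scale. The median was 1.80, and 1.44 with slide as a block (adjusted p = 1.46e-05 with the preset and adjusted p = 0.129 with an estimated correlation). Of 23 expansin and XTH genes, which loosen cell walls, 20 fell, 1 rose and 2 did not pass, with the same counts adjusted over the list alone. EXPA8 fell by 5.31 ± 0.38 and XTH16 by 4.09 ± 0.26, and XTH22, chosen after its values were seen, rose by 2.26 ± 0.37. The median was -1.99, and -1.83 with slide as a block (adjusted p = 4.23e-09 with the preset and adjusted p = 0.134 with an estimated correlation).

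Of 18 aquaporin genes, 13 fell, 1 rose and 4 did not pass, and 15 fell and 1 rose adjusted over the list alone. TIP1;2 fell by 3.48 ± 0.32 and PIP2;3 by 3.01 ± 0.27 on the log2 scale. PIP1;4, chosen after its values were seen, rose by 0.55 ± 0.16, a call lost with slide as a block and without late drought replicate 1 or 2. The median was -1.71, and -1.35 with slide as a block (adjusted p = 2.24e-05 with the preset and adjusted p = 0.227 with an estimated correlation). Of 15 cell cycle genes, 12 fell and 3 did not pass, with 12 adjusted over the list alone. PCNA1, of DNA replication, fell by 2.99 ± 0.24 and the cyclin CYCA1;1 by 2.42 ± 0.20. The median was -1.41, and -1.65 with slide as a block (adjusted p = 3.58e-05 with the preset and adjusted p = 0.0755 with an estimated correlation). Of 8 type-A response regulators, genes induced by cytokinin, 7 fell and 1 did not pass, and 8 fell adjusted over the list alone. ARR15 fell by 3.15 ± 0.42 and ARR16 by 2.24 ± 0.35. Their median was -1.63, and -1.18 with slide as a block, where 3 of the 8 genes passed (adjusted p = 0.00174 with the preset and adjusted p = 0.225 with an estimated correlation).

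Of the 47 ribosomal proteins measured, 37 fell and 10 did not pass, and 40 fell adjusted over the list alone. Those with the smallest p, RPL15 at -2.61 ± 0.20 and RPL12-C at -2.43 ± 0.22, are chloroplast ribosomal proteins. The median was -1.06, and -0.73 with slide as a block, where 13 genes passed (adjusted p = 6.53e-09 with the preset and adjusted p = 0.153 with an estimated correlation). Of 21 glucosinolate genes, 16 fell and 5 did not pass, with 16 adjusted over the list alone. BCAT4 and SOT17, of glucosinolate synthesis, fell by 1.81 ± 0.20 and 1.83 ± 0.21. The median was -1.10, and -1.40 with slide as a block (adjusted p = 3.58e-05 with the preset and adjusted p = 0.153 with an estimated correlation).

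Of 12 heat shock genes measured, 11 rose and 1 did not pass, with 11 adjusted over the list alone. HSP70 rose by 5.18 ± 0.26 and HSP21 was at least 59.1-fold higher in the main scaling. The smallest rise of HSP21 in other settings was 3.28 on the log2 scale. The median was 2.22, and 2.11 with slide as a block (adjusted p = 1.88e-06 with the preset and adjusted p = 0.0755 with an estimated correlation). Of 16 salicylate defence genes, 9 rose, 1 fell and 6 did not pass, and 10 rose and 2 fell adjusted over the list alone. The regulator CBP60G rose by 2.51 ± 0.22 and PR2 by 3.44 ± 0.52, and WRKY54 fell by 2.06 ± 0.35. The median was 1.36, and 0.96 with slide as a block, where 4 genes rose and 1 fell (adjusted p = 0.00207 with the preset and adjusted p = 0.316 with an estimated correlation). Of 13 clock genes, 6 rose and 7 did not pass, with 7 that rose adjusted over the list alone. ELF4 rose by 2.41 ± 0.22 and GI by 1.95 ± 0.25. The median was 0.67, and 0.54 with slide as a block (adjusted p = 0.00142 with the preset and adjusted p = 0.0556 with an estimated correlation). Of 7 hypoxia genes, 5 rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone. ADH1 rose by 3.22 ± 0.38 and SUS1 by 2.62 ± 0.30, and the haemoglobin HB1 fell by 1.90 ± 0.26. This list's median was 1.02, and 0.84 with slide as a block (adjusted p = 0.0285), where 3 genes rose and 1 fell. Its call was lost in 9 of 24 alternatives (adjusted p = 0.0478 with the preset and adjusted p = 0.134 with an estimated correlation).

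The other 8 lists did not pass as groups in the late comparison, with adjusted p from 0.0788 for raffinose and sugar genes to 0.949 for cuticle genes. Of 10 raffinose and sugar genes 5 rose, 1 fell and 4 did not pass, and 5 rose and 2 fell adjusted over the list alone. BAM1 and AMY1, of starch breakdown, rose by 2.40 ± 0.20 and 2.84 ± 0.40. Of 12 cuticle genes 3 rose, 5 fell and 4 did not pass, with the same counts adjusted over the list alone, and the list's median of -0.14 lies below 0 while its test points upwards. LTP4 and LTP3 of the cuticle list rose by 6.25 ± 0.24 and 3.87 ± 0.26, while MAH1 fell by 2.59 ± 0.31. Of 15 redox genes 8 rose, 5 fell and 2 did not pass, with the same counts adjusted over the list alone (adjusted p = 0.358), and 3 rose and 3 fell with slide as a block. ZAT10 rose by 3.25 ± 0.27 and TAPX fell by 2.06 ± 0.21. Of 13 auxin genes 2 rose, 6 fell and 5 did not pass, with the same counts adjusted over the list alone (adjusted p = 0.0974), and 1 rose and 3 fell with slide as a block. IAA29 fell by 4.12 ± 0.21.

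Of 19 jasmonate genes 3 rose, 4 fell and 12 did not pass at day 11, with the same counts adjusted over the list alone (adjusted p = 0.816). PDF1.2A fell by 5.36 ± 0.70 and JAZ10 by 2.25 ± 0.33, and JAZ1 rose by 3.62 ± 0.75, a call lost with slide as a block. With slide as a block the jasmonate list had a median of -1.08 and passed (adjusted p = 0.00604), against 0.19 without. Among markers of other cell types, MYB60 of guard cells fell by 2.42 ± 0.40, CASP1 of roots by 2.09 ± 0.28, and AG of flowers by 1.51 ± 0.21, which was lost under quantile normalisation. Of 7 guard cell genes 1 rose and 2 fell, of 6 root markers 1 fell and of 4 flower or seed markers 1 fell, and adjusted over the list alone 0 rose and 2, 1 and 1 fell. The guard cell, root, and flower or seed lists had medians of -0.29, -0.72 and -0.64 and adjusted p of 0.602, 0.133 and 0.386.

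**Figure D3:**
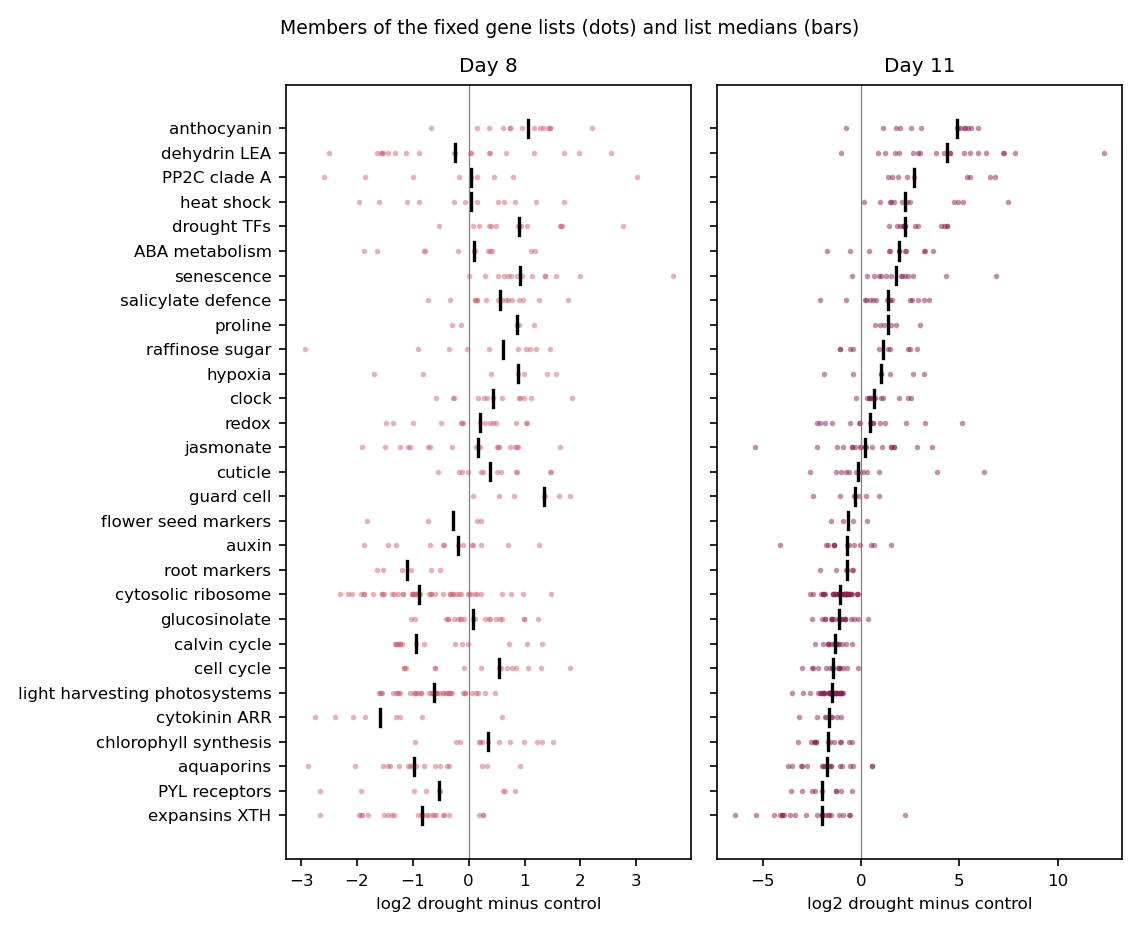
Each dot is the log2 difference of drought minus control of a list member at day 8 (left) or day 11 (right), and each bar is the list's median, with lists ordered by the day 11 median. At day 11 anthocyanin genes have the highest median (4.90) and expansin and XTH genes the lowest (-1.99). With slide as a block, not plotted, the dehydrin median (4.26) is above that of anthocyanin (3.99). At day 8 light-harvesting genes have a median of -0.62 that is 0.37 under quantile normalisation.

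After 8 days without water, genes were called between drought and control shoots, and each of the calls named here was lost without 2 early control arrays of low signal. Among called genes with a symbol that were above background on all 6 arrays and whose groups did not overlap, the largest rise was HB7, a transcription factor induced by water deficit, at 2.76 ± 0.46 (n = 3). ABCF5 rose by 2.59 ± 0.47, the dehydrin ERD10 by 2.54 ± 0.45, ATSDI1 by 2.54 ± 0.42, CLPR1 by 2.53 ± 0.49 and TPLATE by 2.46 ± 0.40. The largest falls among these genes were -2.90 ± 0.58 for CLPB2, -2.87 ± 0.52 for the vacuolar aquaporin TIP2;1, -2.83 ± 0.61 for UNE14, -2.81 ± 0.63 for GH9A3, -2.75 ± 0.45 for the cytokinin-induced ARR6 and -2.71 ± 0.35 for GASA6. In the main scaling the nitrate transporter NRT1.6 was at least 6.53-fold lower, and GLYI7 and RIP3 were at least 2.56-fold and 2.50-fold higher. The smallest log2 differences in other settings were -0.81, 0.96 and 0.95. These fall short of the bounds, whose sizes are 2.71, 1.36 and 1.32 on the log2 scale. The call of GLYI7 was lost with normexp and with the mean of its probes.

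In total 8909 genes were called at day 8, 3915 higher and 4994 lower, with limma. Without early control replicates 1 and 3, an alternative chosen after seeing the data, limma called 0 genes, with 3643 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0522. With the background filter recomputed on the arrays kept, it called 49 genes, 12 higher and 37 lower. In that fit the lone early control is assumed to vary like the other groups. Over the 8909 genes the median size of the folds was 1.09 (SE 0.28), and 0.62 (SE 0.32) without those arrays, where HB7 had 1.75 (adjusted p = 0.230), ERD10 1.24 and ARR6 -1.78. The 8909 genes were called with the dim arrays included, so part of the smaller size without them is built in. With array signal as a covariate 3 genes were called, where the median size was 0.29 (SE 0.26). With the row on the slide as a block limma called 0, with 5303 at an unadjusted p under 0.05, and the median size was 1.25 (SE 0.53). All early controls lie in row 2 and all early drought arrays in row 1. The row estimate thus rests on late control replicate 2, the only late array in row 2, and cannot separate row from drought. Each of the early calls named here was lost in those fits. Leaving out early control replicate 1 gave 4838 calls, replicate 3 gave 4304, early drought replicate 2 gave 5030 and replicate 3 gave 5457. The share of called genes that were higher was 43.9%, but 54.5% under quantile normalisation, where the median over all genes was 0.13 against -0.03, and 29.3% without a background filter, where that median was -0.35.

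The markers chosen beforehand did not move together at day 8. RD29A rose by 1.16 ± 0.33 and P5CS1 by 0.86 ± 0.27, while RAB18 fell by 1.65 ± 0.39. RD29B had a difference of -2.50 ± 1.02 (adjusted p = 0.0627) and NCED3 of -0.19 ± 0.27 (adjusted p = 0.574), and neither passed. RD29B passed in 6 of 22 other settings: slide as a fixed or a random block, normexp, an intensity trend, only the arrays compared, and without early control replicate 2. The call of RAB18 was lost under quantile normalisation and normexp. The calls of RD29A and P5CS1 were lost without early control replicate 1 or 3 and without early drought replicate 2 or 3. With the mean of all probes of the gene in place of the brightest, RAB18 had 0.46 and P5CS1 had -0.52.

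Of the 29 lists, 9 passed camera at day 8, 4 upwards and 5 downwards, and 0 passed with an estimated correlation, where fry passed 15. Without the dim arrays 11 lists passed, and 8 of the 9 did so in the same direction, the exception being guard cells. No member of any list was called without those arrays at the gene set of all 12 arrays, and with the background filter recomputed on the arrays kept HAI2 of the PP2C list was called. These fits share the drought arrays and early control replicate 2 with the comparison of all 6 arrays, so a like direction is in part built in.

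Of 14 drought transcription factors, 7 rose and 7 did not pass, with the same counts adjusted over the list alone. Beside HB7, HB12 rose by 1.64 ± 0.35 and RD26 by 0.94 ± 0.26, a call lost without early control replicate 3 or early drought replicate 2. The median was 0.89, and 0.62 without the dim arrays (adjusted p = 0.00443, and adjusted p = 0.547 with an estimated correlation). The list did not pass with array signal as a covariate. Of 14 senescence genes, 7 rose and 7 did not pass, with 8 that rose adjusted over the list alone, among them PAO at 0.95 ± 0.18 and NAP at 1.99 ± 0.43. The median was 0.91, and 0.63 without the dim arrays (adjusted p = 0.00138, and adjusted p = 0.547 with an estimated correlation). Of 14 anthocyanin genes, 6 rose and 8 did not pass, with 7 that rose adjusted over the list alone, such as CHS at 1.47 ± 0.30 and F3H at 1.42 ± 0.26. The median was 1.07, and 0.71 without the dim arrays (adjusted p = 0.00716, and adjusted p = 0.547 with an estimated correlation). This call was lost with the row as a block, with fry and without early drought replicate 1. Of 7 guard cell genes, 4 rose and 3 did not pass, with 4 adjusted over the list alone, among them MYB60 at 1.38 ± 0.40 and TGG1 at 1.35 ± 0.36. Both calls were lost without early control replicate 1 or 3, and that of MYB60 also without early drought replicate 2 or 3 and with only the arrays compared. The median was 1.35, and 0.56 without the dim arrays, where the list did not pass (adjusted p = 0.0773), nor did it with array signal as a covariate or with only probes above background on all 12 arrays. In the main comparison the guard cell list had an adjusted p = 0.0203, and adjusted p = 0.547 with an estimated correlation.

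Of 23 expansin and XTH genes, 13 fell and 10 did not pass, with 14 that fell adjusted over the list alone. EXPA1 fell by 1.93 ± 0.32 and EXPA11 by 2.66 ± 0.47. The median was -0.83, and -0.82 without the dim arrays (adjusted p = 0.000732, and adjusted p = 0.547 with an estimated correlation). Of 18 aquaporins, 10 fell, 1 rose and 7 did not pass, and 13 fell and 1 rose adjusted over the list alone, with TIP1;1 at -1.44 ± 0.27. The median was -0.98, and -0.59 without the dim arrays (adjusted p = 0.00443, and adjusted p = 0.547 with an estimated correlation). This call was lost without a background filter and with array signal as a covariate. Of 8 type-A response regulators, 7 fell and 1 did not pass, and 7 fell and 1 rose adjusted over the list alone, with ARR4 at -2.39 ± 0.46. The median was -1.58, and -0.89 without the dim arrays (adjusted p = 0.00877, and adjusted p = 0.547 with an estimated correlation). It was lost without a background filter. Of 47 ribosomal proteins, 29 fell, 3 rose and 15 did not pass, and 30 fell and 4 rose adjusted over the list alone. RPS28 fell by 1.93 ± 0.29 and RPS18C by 1.55 ± 0.26. The median was -0.90, and -0.64 without the dim arrays (adjusted p = 3.79e-05, and adjusted p = 0.547 with an estimated correlation).

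Of 40 light-harvesting and photosystem genes at day 8, 19 fell and 21 did not pass, with 19 adjusted over the list alone, among them LHCB1.1 at -1.59 ± 0.39 and PSBR at -1.61 ± 0.41. The median was -0.62, and -0.40 without the dim arrays (adjusted p = 0.000936, and adjusted p = 0.667 with an estimated correlation). This direction turned with the scaling: the list passed upwards under quantile normalisation (median 0.37), under normexp (0.37) and with array signal as a covariate (0.08), and it did not pass with fry. The calls of LHCB1.1 and PSBR were lost under quantile normalisation and normexp, and that of PSBR without early control replicate 3. The dehydrin list did not pass at day 8 (median -0.25, adjusted p = 0.603), with 4 members that rose and 7 that fell, also adjusted over the list alone. COR47 rose by 1.70 ± 0.33, and SAG21 and DI21 fell by 1.45 ± 0.29 and 1.54 ± 0.35. The other 19 lists did not pass either, with adjusted p from 0.0537 for root markers to 0.937 for abscisic acid metabolism. The root markers, of which CASP1 had -1.03 ± 0.28 and CASP2 -1.20 ± 0.32, had a median of -1.11, and -0.41 without the dim arrays. The calls of CASP1 and CASP2 were lost without early control replicate 1, that of CASP1 also without early drought replicate 2 or 3 and that of CASP2 without early control replicate 3.

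The response differed between days for the dehydrins, which were higher in drought at day 11 and not as a group at day 8. Dehydrin genes were also lower in watered shoots at day 11 than at day 8 (median -1.88), which enters this difference. The design does not separate days without water from plant age or a possible difference in time of day at harvest. Tested as late minus early response, TSPO differed by 9.27 ± 0.64, RD29B by 8.47 ± 1.44, LEA4-5 by 7.53 ± 0.56 and HVA22B by 7.49 ± 0.67. In the other direction XTH6 differed by -6.04 ± 0.71, BRS1 by -5.34 ± 0.42, MEE3 by -5.07 ± 0.51 and PKS1 by -4.97 ± 0.58. This difference was called for 6329 genes, 2902 higher and 3427 lower, and for 3849 without early control replicates 1 and 3. It was called for 3717 genes with the row on the slide as a block and for 9783 without early control replicate 2.

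Of the lists, 16 passed this test, and 4 of them also with an estimated correlation: dehydrins, 17 of 20 members higher and 1 lower (median 5.24, adjusted p = 0.0276), abscisic acid metabolism (1.72, adjusted p = 0.0394), PP2C phosphatases (2.55, adjusted p = 0.0276) and chlorophyll synthesis (-1.92, adjusted p = 0.0394). Light-harvesting genes differed by a median of -0.84 (adjusted p = 8.85e-06 with the preset and adjusted p = 0.523 with an estimated correlation). Without early control replicates 1 and 3 these 4 lists did not pass with an estimated correlation (adjusted p = 0.0598 for each). The ribosomal list did not pass (median -0.11, adjusted p = 0.102), nor did it with an estimated correlation. Its median was -0.39 without those arrays.

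Genes called on both days in the same direction numbered 3307, of which 1277 were higher and 2030 lower, against 849 and 1319 if the calls were independent. Genes called in opposite directions numbered 872, against 2117. On both days the control arrays tended to have lower signal than the drought arrays. A shared drought response is thus not separated here from array signal. HB7, ERD10 and TIP2;1 are among the genes called on both days in the same direction, and RAB18 among those called in opposite directions, all 4 chosen after their values were seen. The day 8 call of RAB18 was lost under quantile normalisation. With the mean of all its probes, the day 8 difference of RAB18 was 0.46, the direction of day 11. Across genes, which are not independent replicates, the log2 differences of the 2 days had a Pearson correlation of 0.279 and a Spearman correlation of 0.333. Without early control replicates 1 and 3, where limma called 0 early genes, the shared count was 0 and the Pearson correlation 0.400. With array signal as a covariate, where 3 early genes were called, the shared count was 2. With slide as a block the shared count was 1445. It was 2131 without early control replicate 1, 2002 without early control replicate 3 and 1988 without early drought replicate 2.

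Watered shoots also differed between day 8 and day 11. GBSS1, a starch synthase, was higher at day 11 by 6.52 ± 0.31, the flavonoid gene F3H by 5.47 ± 0.26, the light-stress protein ELIP1 by 5.07 ± 0.20 and the senescence regulator NAP by 4.84 ± 0.43. The clock gene ELF4 was lower by -8.66 ± 0.22, COR27 by -7.80 ± 0.28, MEE14 by -7.34 ± 0.26 and the RNA-binding protein GRP7 by -6.88 ± 0.30. Chosen after their values were seen, the morning gene LHY was at least 189-fold higher and RVE1 at least 26.9-fold higher at day 11, PRR3 was at least 30.8-fold lower, and the evening gene LUX fell by 6.53 ± 0.19. These bounds hold for the main scaling. The smallest log2 differences in other settings were 5.96 for LHY, 3.40 for RVE1 and -2.27 for PRR3. Of the 19734 genes 10136 were called, 4591 higher and 5545 lower, but 4056 without early control replicates 1 and 3. Among the 8 arrays of slide 1, 6066 were called. The share of called genes that were higher was 45.3%, but 53.2% under quantile normalisation and 32.0% without a background filter.

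**Figure D4:**
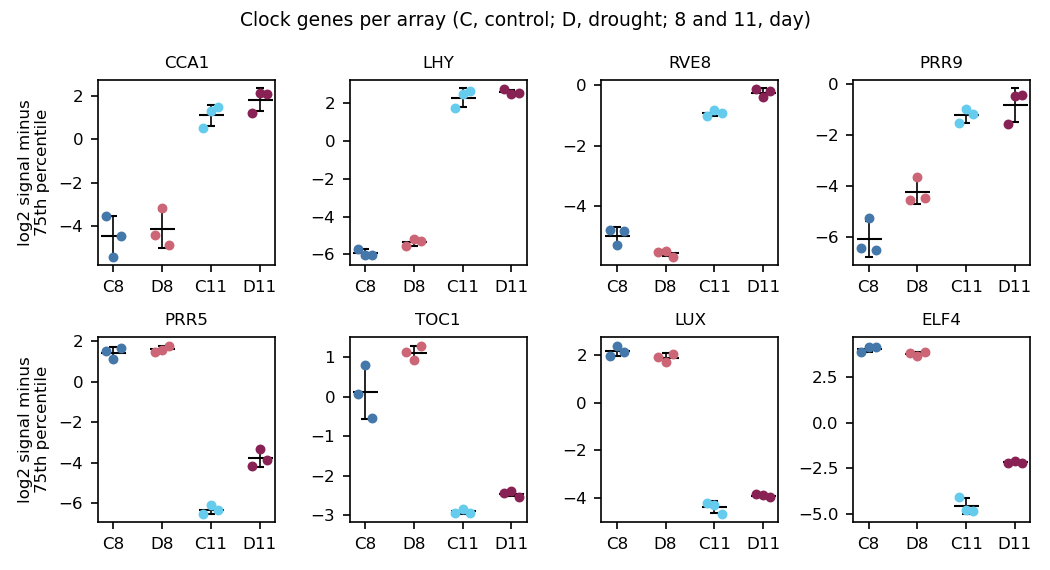
Points are the log2 signal minus the array's 75th percentile of 8 clock genes on each array, with the mean (dash) and SD (bars, n = 3 arrays) of control (C) and drought (D) at days 8 and 11. ELF4 and LUX are lower at day 11 than at day 8 in watered plants, by -8.66 and -6.53, and by -5.98 and -5.77 in drought plants.

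Of the lists, 5 passed camera between the watered controls, and 0 passed with an estimated correlation. These 5 kept their direction without early control replicates 1 and 3, but the counts of members below rest in part on those arrays of low signal. Of 14 anthocyanin genes 12 were higher at day 11 and 2 did not pass, with 14 higher adjusted over the list alone (median 2.23, adjusted p = 4.1e-06, and adjusted p = 0.511 with an estimated correlation). Of 12 cuticle genes 8 were higher and 4 did not pass, with 8 adjusted over the list alone (median 0.83, adjusted p = 0.00351, and adjusted p = 0.284 with an estimated correlation). Of 13 chlorophyll synthesis genes 7 were higher, 2 lower and 4 did not pass, also adjusted over the list alone (median 0.84, adjusted p = 0.0197, and adjusted p = 0.511 with an estimated correlation). Of 47 ribosomal proteins 26 were lower, 2 higher and 19 did not pass, and 27 were lower and 4 higher adjusted over the list alone (median -0.82, adjusted p = 0.00553, and adjusted p = 0.794 with an estimated correlation).

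Of 20 dehydrin and LEA genes 12 were lower in watered shoots at day 11 than at day 8 and 8 did not pass, with 15 lower adjusted over the list alone (median -1.88, adjusted p = 2.01e-05, and adjusted p = 0.284 with an estimated correlation). RAB18 had a mean level of 7.37 ± 0.62 (SD) in early control, 5.72 ± 0.31 in early drought, 2.17 ± 0.80 in late control and 7.42 ± 0.25 in late drought. For this probe, the brightest of the gene, the level in late drought is close to that in early control. These groups lie on different slides, and early control replicates 1 and 3 are of low signal. With the mean of all probes of RAB18 the day 8 difference was 0.46. The clock list did not pass as a group (median -1.97, adjusted p = 0.515), with 5 members higher, 7 lower and 1 not past, also adjusted over the list alone.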

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

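The tests of other sample splits, of the slide in the late comparison and of the row on the slide were planned, and the other tests reported here were chosen after the result was seen, among them the values without early control replicates 1 and 3. The demand that each single drought array meet the bound of the slide test was also added after its values were seen.

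The response to drought differed between day 8 and day 11 by a test of the difference itself for 6329 genes. Days without water are not separated here from plant age or a possible difference in time of day at harvest. The median late minus early difference was 5.24 for dehydrins, 1.72 for abscisic acid metabolism, 2.55 for PP2C phosphatases, -1.21 for PYL receptors and 1.92 for drought transcription factors. It was -0.84 for light-harvesting and photosystem genes, -0.68 for the Calvin cycle, -1.92 for chlorophyll synthesis, 0.71 for senescence, -1.93 for expansins and XTH, and -0.98 for aquaporins. It was 1.80 for heat shock, -1.31 for glucosinolates, 3.35 for anthocyanin, -1.81 for the cell cycle and -0.89 for guard cells. Of these 16 lists 4 passed with an estimated correlation: dehydrins, abscisic acid metabolism, PP2C phosphatases and chlorophyll synthesis. The call of guard cells was lost in 10 of 29 settings, among them without the dim arrays, that of senescence in 7, of the Calvin cycle in 5 and of aquaporins in 4. These 3 were lost with slide as a block, without early control replicate 2 and without late control replicate 1, and that of guard cells without early control replicate 1, early drought replicate 2, late control replicate 3 or late drought replicate 1. Senescence was also lost without late drought replicate 2. Among genes, TSPO differed by 9.27, RD29B by 8.47, LEA4-5 by 7.53 and HVA22B by 7.49, and XTH6 by -6.04, BRS1 by -5.34, MEE3 by -5.07 and PKS1 by -4.97. RD29A differed by 3.37, RAB18 by 6.89, NCED3 by 3.39 and P5CS1 by 2.14.

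Of 100 splits, 1, the real one, gave as many genes for this difference, with 5845 the highest of the others. As many lists as the real 16 came from 48 splits, the highest being 22, so chance is not excluded for the list count. Most other splits mix drought and control arrays in a group. This adds their differences to the spread and lowers the gene count beforehand, so the gene count decides nothing about chance. For genes shared by both days 1 of 100 splits, the real one with 3307, gave as many, and the highest other gave 0. Since the other early and late splits call at most 1 gene each, a count near 0 was fixed beforehand, and this says nothing of sharing beyond the single counts. The 10 splits of 6 arrays are too few for a share under 0.05: the real early count was 8909 and the highest other 1, the late count 9490 and the highest other 0, and the control count 10136 and the highest other 3557. In each of these 3 comparisons 1 split gave as many genes. That highest control split sets early control replicates 1 and 3 and late control replicate 1, the 3 control arrays of lowest signal, against the rest, which points to a structure of the samples. For lists, 3 of 10 splits gave as many as the real 9 at day 8 (highest other 11) and 5 of 10 as many as the real 21 at day 11 (highest other 23).

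The early count moved with the dim control arrays. Against a floor of the dim arrays as the whole cause, 49.6% of genes above background on all 12 arrays were called. Low signal itself stays open: across genes, which are not independent replicates, the differences of dim from brighter arrays within the early controls and within the late controls correlated at 0.508, so part of the early differences may follow array signal. For the row on the slide, the corresponding correlation was -0.749, a sign that the planned test set against the row. It compares 1 late control per row of slide 1, and these differ in signal (624 and 1141). All early controls lie in row 2 and all early drought arrays in row 1, so the row cannot be told apart from drought. The same late controls enter the signal test with the sign swapped. Across genes, early control minus drought therefore went with dimmer minus brighter late control, the direction of array signal. A response to drought stays open too. The folds that follow are those of the 8909 genes called with all 12 arrays, a choice that favours larger folds in that fit. Without the dim arrays the folds were smaller (median size 0.62, SE 0.32, against 1.09, SE 0.28), and with array signal as a covariate they were 0.29 (SE 0.26). With the row as a block they were 1.25 (SE 0.53), but that row estimate rests on late control replicate 2 alone and decides nothing.

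Clock genes moved between the harvests in watered plants. Over 8 dawn and 8 evening genes listed after the clock genes were seen, the shift of dawn minus evening medians was 7.17 in watered plants. It was 6.77 within slide 1 and 6.95 with early control replicate 2 alone, against slide and low signal as the whole cause. In drought plants it was 6.11, so a candidate explanation is that the harvests fell at different times of day, which the labels do not state. The drought arrays of the 2 harvests lie on different slides, so the shift in drought plants is not separated from slide. The evening genes COR27, GRP7 and PRR3 are also named for their falls in watered plants, and without them the 4 shifts were 5.79 in watered plants, 5.53 within slide 1, 5.13 with early control replicate 2 alone and 5.03 in drought plants. Plant age is not separated from the harvest in this design.

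The late response is confounded in part with slide. Array signal as the whole cause is argued against by 10937 genes called with it as a covariate. The slope of folds within slide 2, against its 1 control, on folds against the controls of slide 1 was 0.811, which meets the bound set for it, but 0.732 to 0.878 for single drought arrays, a range that crosses that bound. Both sets of folds share the 3 drought arrays, which builds in part of the slope, so it decides nothing. Over the 9897 genes called against the slide 1 controls the median size was 1.34, and 0.95 against the slide 2 control. These genes were chosen by their calls against the slide 1 controls, which favours larger folds there. A contribution of slide to the size of the folds cannot be told apart from that choice or from the variation of the 1 control array on slide 2.

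Among 4858 tested probes without a named locus, 499 were at least 2-fold higher in late drought than in late control and called, and 923 at least 2-fold lower, a signal in probes that the gene comparisons leave out.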

How the results depend on the processing

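Values without early control replicates 1 and 3, with array signal as a covariate, with normexp on the median signal, and with the row as a block except for the control comparison, were chosen after seeing the data. The planned normexp on the mean signal was not run, because the files hold no such column. Scan could not be separated from slide, the late drought arrays against the 1 control of their slide give the estimate of the slide block, and the late minus early response has no fit on fewer groups.

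The early count was 0 with the row as a block (limma, 5303 at an unadjusted p under 0.05), 3 with the signal covariate, 0 without early control replicates 1 and 3 (limma, 3643 at an unadjusted p under 0.05), 49 with the background filter on the arrays kept, and 5150 with a 2-fold threshold. The late count was 4676 with slide as a fixed block and 6198 with a 2-fold threshold. The late minus early count was 3717 with the row, 3849 without the dim arrays and 3889 with the filter on the arrays kept. The control count was 5664 with the row, 4740 with the signal, 4056 and 4122 without the dim arrays, 6420 with only the arrays compared and 6513 with a 2-fold threshold. The shared count was 1445 with slide as a fixed block, 0 with the row, 2 with the signal, and 0 and 17 without the dim arrays, and limma's early counts at an unadjusted p under 0.05 behind these values of 0 were 5303 and 3643. Lists at day 8 numbered 14 with normexp, 0 with an estimated correlation and 15 with fry. With an estimated correlation they numbered 2 at day 11 and 4 for late minus early. The 2-fold threshold only removes genes; for the others the cause was not tested.

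With the signal covariate RD29B had 0.074, NCED3 0.73 and PSBR 0.013 at day 8. NCED3 had 0.33 without the dim arrays under both filters. With the mean of all probes RAB18 had 0.46 and P5CS1 -0.52. These are the 7 values of named genes that reversed. Of the others 3369 kept direction and side of the threshold, 215 fell short of it and 6, all of RD29B at day 8, newly passed it. The cause was not tested.

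With 1 array left out, the early count ran from 4304 (without early control replicate 3) to 11681, late from 7458 to 9897, late minus early from 4570 to 9783 (without early control replicate 2), control from 7421 to 12350 and shared from 1988 (without early drought replicate 2) to 4465. The early count was 4838 without early control replicate 1, 5030 without early drought replicate 2 and 5457 without replicate 3, and the shared count was 2131 and 2002 without early control replicates 1 and 3. Lists ran from 9 to 11, 20 to 21 and 13 to 18. Of 18 pairs of arrays with the same replicate number, 14 had deviations from the group means that correlated across genes above 0.1, with a range from -0.379 to 0.652. Of the 12 arrays 8 correlated best with their own number, a hint from the data and not from the design. The numbers were not treated as pairs because not every pair passed 0.1. Replicate 1 has the lowest signal in early drought, late control and late drought. Early control replicate 3, also of low signal, correlated with these arrays at 0.295, 0.449 and 0.331. With replicate 3 of those groups it had -0.07, -0.379 and -0.238, so the hint cannot be told apart from array signal. With replicate number as a block the counts were 10142, 10536, 7700, 11268 and 4167, and 10, 20 and 15 lists. Single early controls gave 8636, 0 and 9607 genes for replicates 1, 2 and 3, the 0 with limma and 3643 at an unadjusted p under 0.05, and single late controls 9462, 6289 and 4766. Signal over background limits the early comparison, with 36260 and 36218 spots above it on early control replicates 1 and 3.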

Other observations

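The list of clock output genes used here and its test were chosen after the clock genes were seen.

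For genes that cycle with the day, the late minus early values of watered and drought plants are set side by side, and in drought plants they were not tested. The early and the late drought arrays also lie on different slides. COL1 had 4.58 in watered and 4.28 in drought plants, and CDF1 2.53 and 2.40. The RNA-binding proteins GRP7 and GRP8 had -6.88 and -5.73, and -3.19 and -2.84, and COR27 had -7.80 and -6.92. The median over 8 dawn genes was 2.60 in watered and 2.43 in drought plants, and over 8 evening genes -4.56 and -3.69. Other pairs of values lay further apart: BOA had -4.09 in watered and -2.47 in drought plants, and ELF4 -8.66 and -5.98, a difference with an adjusted p of 8.2e-05 by limma. RVE2, with -0.62 in watered and 1.25 in drought plants, and CKB4, with -0.43 and 0.01, did not pass in watered plants (adjusted p = 0.0939 and adjusted p = 0.0788).

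Early control replicates 1 and 3 correlated with each other across genes at 0.992 and with replicate 2 at 0.953 and 0.944. Replicate 2 correlated with the 3 early drought arrays at 0.979, 0.966 and 0.972, above its values with the other early controls. The first principal component over genes held 64.1% of the variance and the second 17.3%.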
